A study of Mus musculus with 7 samples.

How the data were processed

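Bulk RNA sequencing was done on RNA from light zone germinal centre B cells that were sorted from mouse spleens into a lysis buffer, and the labels give the molecule as polyA RNA. The 7 samples were grouped by the genotype label, 3 as MIZ1KO and 4 as Control, and were named by their genotype and the replicate number in the labels.

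One table holds expected counts, estimated reads per gene that need not be whole, which the authors deposited without normalization. STAR 2.5.2, RSEM 1.3.0 and the mouse build GRCm38 are named in the submitters' processing notes, which give them no role or order. The annotation release, the strand setting and the treatment of reads that match several genes are not given in the sources used here, so counts of overlapping genes, antisense models and near-identical copies are uncertain. The other table holds log2 values across the 7 libraries, deposited by the authors under a name that speaks of variance stabilisation, and DESeq2 1.18.1 and R 3.4.3 are named per the submitters' processing notes. The function behind these log2 values is not given in the sources used here, and they entered as an alternative.

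The count table lists 48795 gene identifiers, of which 28933 had no counts in any library. Symbols, classes, coordinates, exonic length and GC content came from GENCODE vM21 on GRCm38 and from a table of gene names, and 48349 identifiers matched a symbol while 446 did not. Of the values, 6.61% were not whole; counts were rounded to whole numbers before the tests, which moved none by more than 0.5. Around 50% of the counts lay in ribosomal RNA models, which sets the useful depth to between 3087992 and 5085019 counts per library. Counted here as ribosomal RNA were the annotation's classes of ribosomal and mitochondrial ribosomal RNA and, added by name, the gene Gm26917. Intervals on shares are exact 95% binomial intervals (Clopper-Pearson) and cover counting error only.

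Genes were filtered with filterByExpr, libraries were scaled by the trimmed mean of M-values (TMM), and the groups were compared with the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with robust dispersion and robust quasi-likelihood estimation, two-sided and with Benjamini-Hochberg adjustment over 11618 genes. The design fixed in advance asked for the edgeR 4 quasi-likelihood fit and listed the legacy fit as its alternative. Since the legacy fit is the default of the installed version, the newer fit was chosen by its setting; it called 692 genes and the legacy fit 468. Standard errors were derived from the log2 fold change and the F statistic. CPM values use the TMM-scaled library sizes, and a prior count of 2 was added for log2 CPM.

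Gene lists were fixed before the data were examined, 35 in all, and cover germinal centre zones and identity, MYC and MIZ1 targets, B cell receptor signalling, calcium, apoptosis, p53, cell cycle, NF-kB, plasma and memory cell genes, metabolism, interferon, autophagy, ribosomal proteins, antigen presentation, class switching, immunoglobulin constants, immediate early genes and markers of other cells. Lists with at least 3 tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over 27 lists, with 4 lists of other cell types as a family of their own. An estimated correlation, fry and a rank-based camera were alternatives, and with the estimated correlation 0 of the 27 lists passed, with a lowest adjusted p of 0.487, while camera with the preset value called 8 and fry called 2. Fry asks whether the genes of a list move one way on balance, without setting them against other genes.

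Named genes followed a rule fixed before the data were examined. Zbtb17 and Tmbim4 came first. Then, among genes with an adjusted p under 0.05, a mean of at least 10 CPM over the 7 samples and no overlap of CPM between the groups, and leaving out V, D and J segments and predicted genes, the 12 with the largest positive and the 12 with the largest negative log2 fold change were taken. For each list up to 4 members with the smallest p were added. Any member of the lists of other cell types and of sex-linked genes could be given as a level. The genes named beside Zbtb17 on chromosome 4 other than Dhrs3 were chosen after their values were seen.

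Isotype shares were the counts of each heavy chain constant gene over the sum of 8 such genes per library, compared with a two-sided exact permutation test over 35 splits, whose smallest p is 0.0286, and adjusted over the 8 genes. The same test compared 10 library quantities.

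Libraries were checked for duplicates. Spearman correlations of log2 CPM across genes lay between 0.906 and 0.949 within groups and between 0.882 and 0.935 between groups, and the lowest chi-square per degree of freedom within a group was 16.1, so no pair agreed within sampling noise and each library counted once. The first principal component of log2 CPM held 36.4% of the variance and separated the groups. It also ordered the libraries, within each group too, as the nuclear RNA index described below does. This axis therefore does not tell genotype apart from the nuclear RNA share.

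The gene and list tests were tested on simulated data for the comparison of MIZ1KO with Control, as 10 sets of 11618 genes with 200 genes changed in each. At a 2-fold change 27.4% of changed genes were recovered and at a 4-fold change 75.5%, and 7.33% of calls were unchanged genes. Each set also held a list of 30 further genes with a small shift, not counted as unchanged. Camera called that list in 10 of 10 sets and 0 of 190 lists with no shift. The simulated genes were drawn independently of each other. In the real lists of the main family the estimated inter-gene correlation ran from -0.008 for calcium handling to 0.927 for ribosomal protein genes. These rates therefore do not show how often camera calls lists whose genes move together.

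Alternatives fixed before the data were examined were other scalings (RLE size factors and library totals), no filter and a filter of at least 5 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, the legacy fit, the deposited log2 values in limma, leaving out immunoglobulin genes, a replicate block, a minimum fold change of 1.5, and each library left out in turn. After seeing the data 4 were added: leaving out ribosomal RNA genes, protein-coding genes only, a loess correction of each library for GC content and exonic length, and a nuclear RNA index, the mean log2 CPM of 537 TEC models, as a covariate.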

Results

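Gene expression was measured by bulk RNA sequencing in light zone germinal centre B cells, the germinal centre B cells that have captured antigen and compete for T cell help, sorted from mouse spleen 10 days after intravenous immunisation with sheep red blood cells, a standard antigen for raising germinal centres. The 7 samples fell into 3 labelled MIZ1KO and 4 labelled Control. MIZ1 is a zinc finger transcription factor encoded by Zbtb17, which activates its own target genes and represses others when bound by MYC. The single comparison of the design asks how loss of MIZ1 alters the transcripts of these cells. Library totals ranged from 6896673 to 9482453 estimated counts, and the counts outside ribosomal RNA from 3087992 to 5085019. The labels call the samples replicates of a genotype without saying that each came from its own animal, so p-values measure the spread between these samples, which may be in part technical.

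In several kinds of RNA the libraries of the groups lay apart, although no library quantity passed its adjusted test. Transcript models of the GENCODE class TEC, mostly unspliced single-exon models that still await experimental evidence, took 0.690% ± 0.204 of the counts outside ribosomal RNA in MIZ1KO (SD, n = 3) and 1.79% ± 0.653 in Control (SD, n = 4). The nuclear non-coding RNAs moved alike: Malat1, a component of nuclear speckles, took 0.352% ± 0.122 against 1.15% ± 0.353, and Xist, which coats the inactive X chromosome, took 0.512% ± 0.109 against 1.6% ± 0.671. Protein-coding genes took 94.4% ± 0.556 against 91.1% ± 1.79. In none of these quantities did the libraries of the groups overlap, and each gave p = 0.0571 in a two-sided exact permutation test over 35 splits, with an adjusted p of 0.114 over 10 library quantities, where the smallest p the design allows is 0.0286. Ribosomal RNA took 50.6% ± 4.98 in MIZ1KO and 50.7% ± 1.80 in Control (exact permutation p = 0.971), and mitochondrial mRNA 1.5% ± 0.341 and 1.52% ± 0.630 of the counts outside it (exact permutation p = 1). The Y-linked genes Kdm5d, Uty and Eif2s3y had no counts in any library, and Ddx3y had counts in MIZ1KO replicate 2 alone, at 0.197 CPM of the counts outside ribosomal RNA.

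**Figure D1:**
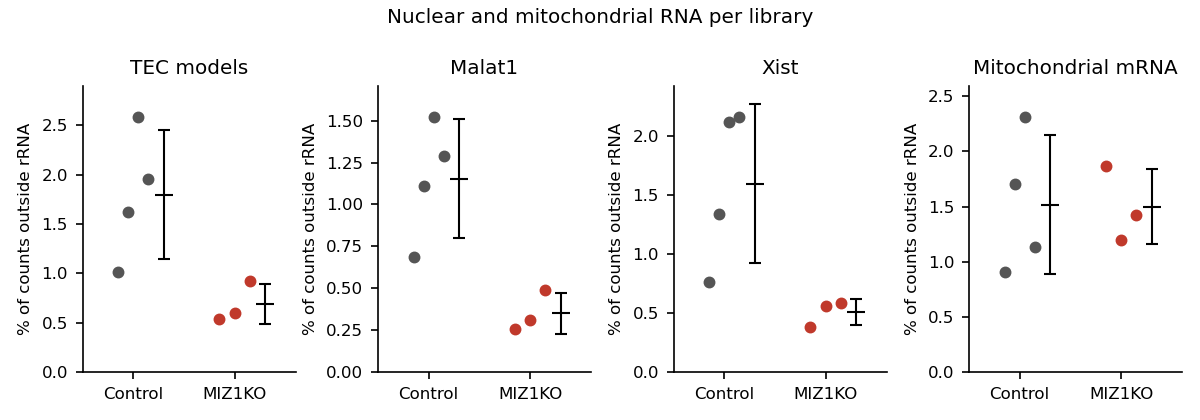
Share of the counts outside ribosomal RNA, in percent, taken by TEC models, Malat1, Xist and mitochondrial mRNA; each point is a library and the bar beside each group is its mean with the SD. TEC models averaged 0.690% in the 3 MIZ1KO libraries and 1.79% in the 4 Control libraries with no overlap, while mitochondrial mRNA averaged 1.5% and 1.52%.

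Zbtb17 itself was measured at 4.45 ± 0.732 CPM, counts scaled to a common library size, in the libraries labelled MIZ1KO (SD, n = 3) and at 4.18 ± 1.89 CPM in Control (SD, n = 4). Its log2 fold change of MIZ1KO over Control was 0.03 ± 0.46 (SE), with an adjusted p of 0.975 by the quasi-likelihood test of edgeR. The gene (ENSMUSG00000006215) lies on chromosome 4 from 141444654 to 141467930 in GRCm38, and the deposited counts cover the whole gene, so transcript outside a deleted part stays in the count and the level does not check the genotype labels. It rested on 22 to 70 counts per library and its model overlaps that of Spen. Tmbim4, a transmembrane BAX inhibitor motif gene of the Golgi that work on MIZ1 in germinal centre B cells has named, was lower in MIZ1KO: 1.13 ± 0.571 CPM against 8.28 ± 6.29 CPM, a log2 fold change of -2.92 ± 0.69 with an adjusted p of 0.0223 (edgeR). All 3 MIZ1KO libraries lay below all 4 Control libraries, which ranged from 3.31 to 17.4 CPM. Tmbim4 (ENSMUSG00000020225) lies on chromosome 10 from 120201590 to 120224917, where its model overlaps that of Irak3, and reads from the overlap cannot be assigned with certainty. Irak3, chosen after its values were seen, measured 2.03 ± 0.68 (adjusted p = 0.0778, edgeR). Because the study may have picked Tmbim4 on these same libraries, its fall is not independent evidence. The call ended without MIZ1KO replicate 1 (adjusted p = 0.118), without MIZ1KO replicate 2 (0.0782), in limma-voom (0.0907) and against a minimum fold change of 1.5 (0.0957). Over its alternatives the log2 fold change of Tmbim4 ran from -5.56 with the nuclear RNA index to -0.82 on the deposited log2 values.

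Of 11618 genes tested, 692 passed an adjusted p of 0.05 in edgeR, 221 of them higher and 471 lower in MIZ1KO. Protein-coding genes were called in equal measure, 204 higher and 202 lower among 9812 tested, whereas a fit to protein-coding genes only called 140 higher and 175 lower. With all libraries, the excess of lower calls lay in the non-coding classes: 136 of 537 TEC models, 38 of 207 lincRNAs, 34 of 244 antisense models and 17 of 129 processed transcripts were lower, against 2, 6, 0 and 1 that were higher. The median log2 fold change was -1.35 over TEC models and 0.03 over protein-coding genes. Whether the antisense models were counted by strand is not given in the sources used here, so their reads cannot be told apart from those of the sense partner. The number of calls and the balance of directions changed when single libraries were left out, which also leaves fewer samples to test. Without MIZ1KO replicate 1, 39 genes were called, 22 higher and 17 lower, and without MIZ1KO replicate 2, 495 were called, 299 higher and 196 lower, so in both the higher calls were in excess. The lower calls stayed in excess without each of the other libraries, where 317 genes were called without MIZ1KO replicate 3, 1350 without Control replicate 1, 205 without Control replicate 2, 428 without Control replicate 3 and 142 without Control replicate 4. A correction for GC content and length gave 136 higher and 158 lower calls, a more even split.

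Among the genes lower in MIZ1KO, Rsrc1, which encodes an arginine- and serine-rich protein of splicing, fell furthest of those the naming rule took. It measured 2.21 ± 1.65 CPM in MIZ1KO (SD, n = 3) and 26.7 ± 4.30 CPM in Control (SD, n = 4), a log2 fold change of -3.68 ± 0.43 with an adjusted p of 0.000308 (edgeR). Its gene lies on chromosome 3 from 66981390 to 67358396 and overlaps Shox2. Vamp4, a SNARE protein of the trans-Golgi network, fell from 30.7 ± 6.19 to 6.87 ± 3.44 CPM, and Rpl22, a protein of the large ribosomal subunit, from 396 ± 148 to 102 ± 23.8 CPM. Saal1 fell by 1.67 and Snapc3, a subunit of the complex that drives small nuclear RNA transcription, fell by 1.61 on the log2 scale. Rbm3, a cold-induced RNA-binding protein, fell by 1.63 and the chemokine gene Ccl25 fell by 1.66, the latter in an overlap with Elavl1. Usp53 fell by 1.62 and Lrrc18 fell by 1.78. Malat1 and Xist fell by 1.67 and 1.59, and Mypopos, an antisense model of Mypop, fell by 1.93. The adjusted p-values of these 12 genes ran from 0.000308 to 0.0251 (edgeR), and every MIZ1KO library lay below every Control library, as the naming rule required.

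Dhrs3, a short-chain dehydrogenase that reduces retinal, rose furthest of those the naming rule took by size of change. It measured 59.1 ± 18.3 CPM in MIZ1KO (SD, n = 3) and 10.9 ± 1.05 CPM in Control (SD, n = 4), a log2 fold change of 2.45 ± 0.26 with an adjusted p of 0.000139 (edgeR). Dhrs3 lies on chromosome 4 from 144892827 to 144928209, on the chromosome of Zbtb17. Cnbd2, a gene with a cyclic nucleotide-binding domain, rose by a log2 fold change of 2.16 ± 0.35, and Scand1, which overlaps it on chromosome 2, by 1.38 ± 0.38. The metalloprotease gene Adam19 rose by 1.82 ± 0.45, from 43.7 CPM in MIZ1KO replicate 2 and 12.7 and 11.6 CPM in the other MIZ1KO libraries, and by 0.96 without replicate 2 (adjusted p = 0.173). BC030867 rose by 1.78 ± 0.35. Bcat1, the cytosolic branched-chain aminotransferase, rose by 1.46 ± 0.33, Scrib, a cell polarity scaffold, by 1.44 ± 0.38, and Ndufs7, a subunit of respiratory complex I, by 1.42 ± 0.30. Pfdn6, a prefoldin chaperone subunit, rose by 1.5 ± 0.36, Ccdc124 by 1.42 ± 0.34, and ENSMUSG00000064168, an identifier that matched no symbol, by 1.55 ± 0.25. Ighg3, the heavy chain constant gene of IgG3, rose by 1.41 ± 0.20 with an adjusted p of 0.00198 (edgeR), from 43.4 ± 8.49 to 115 ± 4.61 CPM. The other adjusted p-values among these 12 ran up to 0.0421 (edgeR), with no overlap of libraries, which the naming rule required. In all, 172 higher and 147 lower genes met the naming rule. Of all 11618 tested genes, 2267 or 19.5% had no overlap between the groups, where chance gives 5.71% on average over splits. Genes move together across the libraries, so a single split can give a larger share by chance.

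**Figure D2:**
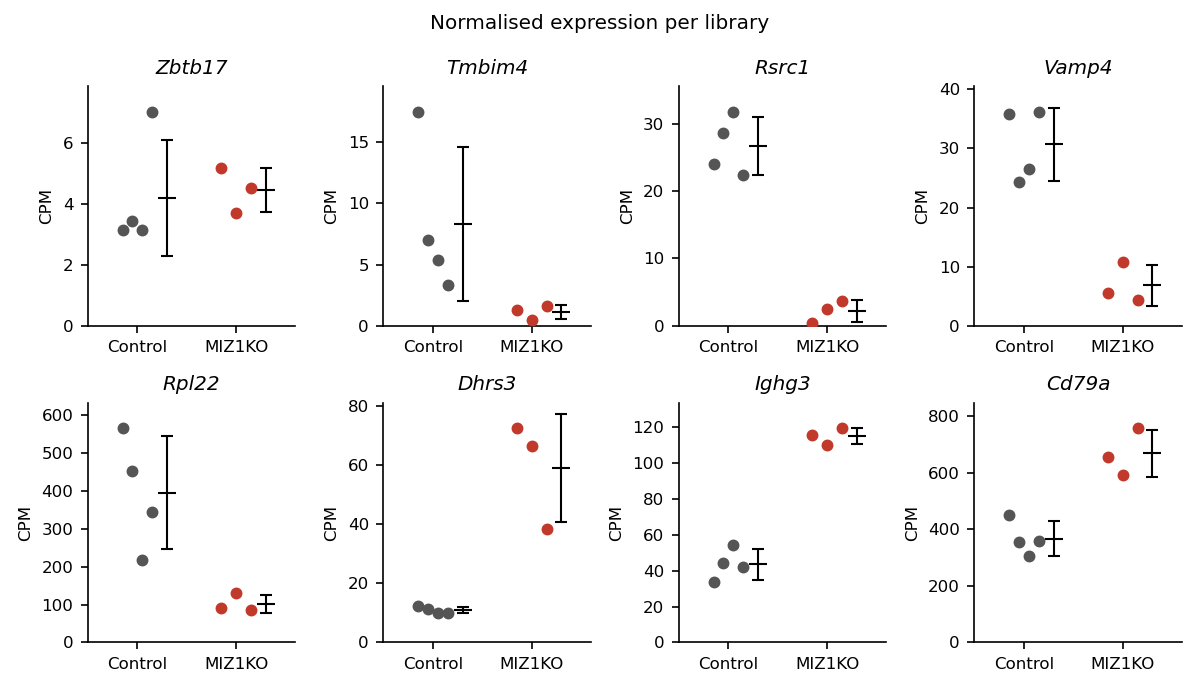
Normalised expression in CPM of 8 genes in each library; points are libraries and the bar beside each group is its mean with the SD. Zbtb17 averaged 4.45 CPM in MIZ1KO and 4.18 CPM in Control, whereas Rsrc1, Vamp4 and Rpl22 lay lower and Dhrs3 and Ighg3 higher in all 3 MIZ1KO libraries than in all 4 Control libraries.

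Of the 45 named genes past the threshold, list members included, 8 kept it whichever library was left out: Dhrs3, Cnbd2, ENSMUSG00000064168, Ighg3, Rsrc1, Vamp4, Rpl22 and Snapc3. Of these, Ighg3 and Rpl22 also kept it in every other alternative that gave them a value. The other 6 lost it with the nuclear RNA index as a covariate, with adjusted p-values from 0.0515 for Vamp4 to 0.640 for Snapc3, and ENSMUSG00000064168 also against a minimum fold change of 1.5 (0.0532). With the index the log2 fold changes were 1.36 for Dhrs3, 1.36 for ENSMUSG00000064168, -2.98 for Rsrc1, -2.63 for Vamp4 and -0.56 for Snapc3, so the change of Vamp4 grew while the others, Cnbd2 included, shrank. As the index did not overlap between the groups, calls that end with it do not tell the nuclear RNA share apart from genotype. Among the 45, the nuclear RNA index ended 39 calls, a minimum fold change of 1.5 ended 36, the correction for GC content and length 22, the replicate block 15, limma-voom 11, the legacy fit 7, library totals 4, no filter 2, and leaving out ribosomal RNA genes and the deposited log2 values 1 each; 4 of 39 ended among protein-coding genes only. Without MIZ1KO replicate 1, 36 of the 45 calls ended, with adjusted p-values of at most 0.178 (edgeR). Leaving out MIZ1KO replicate 2 ended 11 calls (at most 0.173) and MIZ1KO replicate 3 ended 21 (at most 0.158). Leaving out Control replicate 1 ended 0, Control replicate 2 ended 27 (at most 0.133), Control replicate 3 ended 7 (at most 0.0819) and Control replicate 4 ended 26 (at most 0.125).

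Among genes reported as MIZ1 targets, Vamp4 and Rpl22 were lower in MIZ1KO. Of 10 measured members, 4 lay above 0, Vamp4 and Rpl22 fell, by log2 fold changes of -2.12 ± 0.33 and -1.95 ± 0.29, and the other 8 did not pass the test over all genes. Adjusted over the list alone, 3 fell and 0 rose. The autophagy genes Uvrag and Ambra1 measured -0.60 ± 0.20 (adjusted p = 0.0805, edgeR) and -0.65 ± 0.28 (adjusted p = 0.160, edgeR). Camera gave an adjusted p of 0.0477 for the list in the downward direction, with a median log2 fold change of -0.08 and a mean of -0.44, and an adjusted p of 0.525 with an estimated correlation and 0.285 by ranks. Vamp4 (ENSMUSG00000026696) lies on chromosome 1 from 162570515 to 162599084 and Rpl22 (ENSMUSG00000028936) on chromosome 4 from 152325742 to 152334071, 10.9 Mb from Zbtb17 and so on the chromosome of the targeted gene but outside the 10 Mb within which linked genes were counted. Processed copies of ribosomal protein genes can share reads with Rpl22. The list's call ended without MIZ1KO replicate 1 (adjusted p = 0.242), MIZ1KO replicate 3 (0.0989), Control replicate 1 (0.0709) or Control replicate 2 (0.0501). It held among protein-coding genes only (0.0149), after the correction for GC content and length (0.00134) and with the nuclear RNA index as a covariate (0.0455), the TEC share being 0.690% in MIZ1KO and 1.79% in Control.

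Camera with its preset correlation called the MYC-activated, G2/M and G1/S lists higher in MIZ1KO, while few of their members passed on their own. The MYC-activated genes, mostly factors of ribosome assembly and nucleotide synthesis, had a median log2 fold change of 0.36 with 29 of 34 members above 0 (camera adjusted p = 0.000208; adjusted p = 0.525 with an estimated correlation). Over all genes 1 member rose, Cad, the enzyme that begins pyrimidine synthesis, by 0.92 ± 0.26, and adjusted over the list alone 4 rose. The nucleolar genes Fbl and Ddx21 measured 0.74 ± 0.22 and 0.65 ± 0.20 without passing over all genes. The G2/M genes had a median of 0.32 with 21 of 26 above 0 (camera adjusted p = 0.00238; adjusted p = 0.525 with an estimated correlation), and Kif20a, a kinesin of cytokinesis, rose by 1.05 ± 0.29, while adjusted over the list alone 0 passed. The G1/S and DNA replication genes had a median of 0.28 with 19 of 30 above 0 (camera adjusted p = 0.0283; adjusted p = 0.525 with an estimated correlation). Here the replicative helicase subunit Mcm5 rose by 0.82 ± 0.19, the cyclin gene Ccnd3 by 0.82 ± 0.20 and Uhrf1, which maintains DNA methylation, by 0.77 ± 0.19, whereas the thymidine kinase gene Tk1 fell by 0.82. Adjusted over the list alone 5 rose and 2 fell. The G1/S call ended without Control replicate 2 (adjusted p = 0.0501) or Control replicate 4 (0.0517), and it ended among protein-coding genes only (0.128). The TEC share of the MIZ1KO libraries was lower, 0.690% against 1.79%, and with the nuclear RNA index as a covariate camera's direction turned downward for all 3 lists, with adjusted p-values of 0.0668 for MYC-activated, 0.950 for G2/M and 0.691 for G1/S genes. Since the index did not overlap between the groups, this turn cannot tell the nuclear RNA share apart from genotype.

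Of the B cell receptor and its signalling, Cd79a, Ptpn6, Ighg3 and Ighg2b rose in MIZ1KO. The BCR signalling genes had a median log2 fold change of 0.26 with 21 of 25 members above 0 (camera adjusted p = 0.00238; adjusted p = 0.525 with an estimated correlation). Cd79a, which encodes the Ig-alpha signalling chain, rose from 368 ± 60.8 CPM in Control (SD, n = 4) to 669 ± 84.2 CPM in MIZ1KO (SD, n = 3), a log2 fold change of 0.86 ± 0.22 (edgeR adjusted p = 0.0333). Ptpn6, which encodes the phosphatase SHP-1, rose by 0.64 ± 0.18 (edgeR adjusted p = 0.0484), and the other 23 members did not pass over all genes. Adjusted over the list alone 3 members rose. The Ptpn6 call ended when any of 5 libraries was left out and in 9 of 15 other alternatives. That of Cd79a ended when any of 4 libraries was left out and in 4 of 15 other alternatives. Cd79b, the Ig-beta chain, measured 0.80 ± 0.24 (edgeR adjusted p = 0.0556). All 8 heavy chain constant genes were above 0, with a median of 0.72 (camera adjusted p = 0.000208; adjusted p = 0.487 with an estimated correlation). Ighg3 and Ighg2b rose, by 1.41 ± 0.20 and 0.86 ± 0.20, and adjusted over the list alone 4 rose. The Ighg2b call ended when any of 3 libraries was left out and in 2 of 13 other alternatives, while that of Ighg3 never ended. Constant genes are close in sequence, and how shared reads were divided among them depends on the authors' counting. TEC models took 0.690% of the counts outside ribosomal RNA in these MIZ1KO libraries and 1.79% in Control, and with the nuclear RNA index as a covariate the heavy chain constant genes gave an adjusted p of 0.0980 and the BCR signalling genes 0.00990, both upward. That index did not overlap between the groups and cannot be told apart from genotype.

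The shares of the isotypes among heavy chain transcripts were compared in a design that limits what the test can show: the smallest p it allows is 0.0286, and a single isotype at that p would not pass after adjustment over 8. Ighm took 82.9% ± 2.87 of heavy chain constant counts in MIZ1KO (SD, n = 3) and 81.1% ± 1.78 in Control (SD, n = 4), with an exact permutation p of 0.371. Ighg1 took 8.38% ± 2.37 against 11.5% ± 2.07 (exact permutation p = 0.20) and Ighg2b 3.34% ± 0.479 against 2.85% ± 0.306 (exact permutation p = 0.171). Ighg3 took 2.73% ± 0.0454 against 1.63% ± 0.428, with no overlap between the groups and an exact permutation p of 0.0571. Adjusted over the 8 isotypes the lowest p was 0.40, which does not show that the shares were alike. As CPM in place of shares, Ighm, Ighg2b and Ighg3 each gave an exact permutation p of 0.0286 and an adjusted p of 0.0762. The shares rested on 17165 to 39967 constant gene counts per library.

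**Figure D3:**
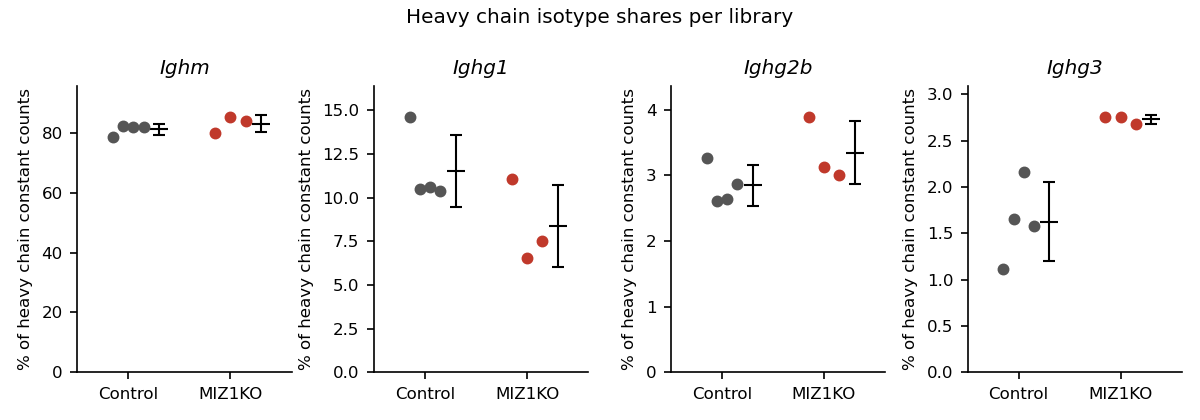
Share of each of 4 heavy chain constant genes in the heavy chain constant counts of each library, in percent; points are libraries and the bar beside each group is its mean with the SD. Ighg3 averaged 2.73% in MIZ1KO and 1.63% in Control without overlap, and the shares of Ighm, Ighg1 and Ighg2b overlapped between the groups.

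**Figure D4:**
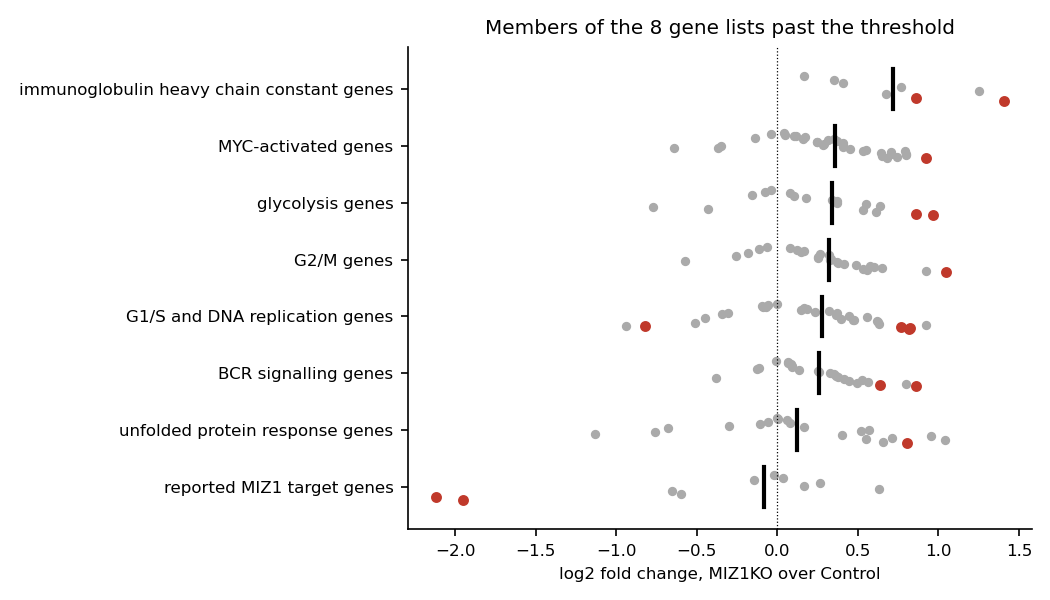
Log2 fold change of MIZ1KO over Control for each measured member of the 8 lists that camera called with its preset correlation; red points are genes past an adjusted p of 0.05 over all genes, grey points the others, and the black line is the list median. Medians ran from -0.08 for the reported MIZ1 targets to 0.72 for the heavy chain constant genes.

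The lists that describe the zones and identity of the germinal centre did not pass camera in the main fit, and that of the dark zone passed in 8 of 24 alternatives. For the light zone genes the adjusted p was 0.933, and of 24 members 1 passed over all genes and 1 adjusted over the list alone. The list had a median of 0.06 and a mean of -0.04, and camera pointed down. The gene that passed was Cd69, an early activation marker, which fell by 1.44 on the log2 scale, from 29.0 ± 4.03 CPM in Control (SD, n = 4) to 10.8 ± 3.45 CPM in MIZ1KO (SD, n = 3; edgeR adjusted p = 0.0143). The dark zone genes had an adjusted p of 0.0555, with Kif20a higher and Rgs13, a regulator of G protein signalling in germinal centre B cells, lower by 1.32 (edgeR adjusted p = 0.0230) among 18 members. Adjusted over the list alone 2 rose and 1 fell. The Rgs13 call ended when any of 4 libraries was left out, and that of Kif20a when any of 6 was. Rgs13 also lost its call after the correction for GC content and length (edgeR adjusted p = 0.754). Its log2 fold change came as near 0 as -0.30 among its alternatives. Many dark zone genes, Kif20a, Plk1 and Mki67 among them, are also in the G2/M list called higher above, so these lists are not independent. The dark zone list passed, upward, with RLE size factors (0.0499), no expression filter (0.00511), the correction for GC content and length (0.000446), ribosomal RNA genes left out (0.0454), limma-voom (0.0398), the deposited log2 values (0.0421) and without MIZ1KO replicate 3 (0.0276) or Control replicate 1 (0.0312), and gave 0.525 with an estimated correlation. Germinal centre identity genes gave 0.142, with Rgs13 again the 1 member of 20 past the threshold, and adjusted over the list alone 2 rose and 2 fell; with no expression filter the list passed upward (0.0246). Mef2b measured 0.81 ± 0.25 and Mybl1 -0.69 ± 0.23, neither past the threshold. Plasma cell genes gave 0.876 with 0 of 12 members called, and 1 higher and 2 lower adjusted over the list alone, and passed downward with the nuclear RNA index (0.0281). Memory B cell genes gave 0.429 with 0 of 15 called, and class switch and somatic hypermutation genes 0.413 with 0 of 18 called; adjusted over the list alone neither had a call. MHC class II presentation genes gave 0.137 with 0 of 13 called, and 1 higher and 2 lower adjusted over the list alone, and passed upward with no expression filter (0.0210) and without Control replicate 1 (0.0258).

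Tpi1, Gpi1 and Hyou1 rose in MIZ1KO, and camera called their lists, glycolysis and the unfolded protein response, higher. Glycolysis genes had a median log2 fold change of 0.34 with 12 of 17 above 0 (camera adjusted p = 0.0477; adjusted p = 0.530 with an estimated correlation), and Tpi1 and Gpi1, both enzymes of its upper steps, rose by 0.97 ± 0.25 and 0.86 ± 0.23, while adjusted over the list alone 3 rose. The unfolded protein response genes had a median of 0.13 with 14 of 20 above 0 (camera adjusted p = 0.0491; adjusted p = 0.525 with an estimated correlation). Hyou1, a chaperone of the endoplasmic reticulum, rose by 0.80 ± 0.22, and adjusted over the list alone 3 rose, whereas Atf4 and Creld2 measured 0.66 ± 0.20 and 1.04 ± 0.33 without passing over all genes. The calls of Tpi1 and Gpi1 each ended when any of 4 libraries was left out, and that of Hyou1 when any of 5 was. They also ended in 3, 5 and 7 of 15 other alternatives. Over its alternatives the log2 fold change of Tpi1 went down to 0.01, with the nuclear RNA index as a covariate. With single libraries left out it ran from 0.87 to 1.23. The glycolysis call ended without MIZ1KO replicate 1 (adjusted p = 0.113), Control replicate 2 (0.0501), Control replicate 3 (0.114) or Control replicate 4 (0.0865). That of the unfolded protein response ended without MIZ1KO replicate 2 (0.0959), Control replicate 2 (0.130), Control replicate 3 (0.0712) or Control replicate 4 (0.0813). Both calls ended among protein-coding genes only (0.128 and 0.167) and after the correction for GC content and length (0.532 and 0.0854). The MIZ1KO libraries held the smaller TEC share, 0.690% against 1.79%, and with the nuclear RNA index as a covariate camera's direction turned downward for both (0.163 and 0.950). Because the groups did not overlap in the index, it cannot be told apart from genotype.

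Of the other pathways, oxidative phosphorylation genes had a camera adjusted p of 0.108, and 1 of 35 members rose, Atp5d, by 0.79 ± 0.23; adjusted over the list alone 0 passed. Mitochondrially encoded genes gave 0.270 with 0 of 13 called and 1 higher adjusted over the list alone, and ribosomal protein genes 0.321 with 0 of 50 called on either basis. NF-kB target genes gave 0.101, and Bcl3, a nuclear member of the IkB family, rose by 1.10 ± 0.25 as the 1 called of 22, as also when adjusted over the list alone. Calcium handling genes gave 0.261, and Calr, which encodes the calcium-binding chaperone calreticulin, rose by 0.81 ± 0.22 as the 1 called of 25 on both bases. Autophagy and lysosome genes gave 0.196. In that list Tfeb, a transcription factor for lysosomal genes, rose by 0.99 ± 0.23 and Atg16l1, needed to lipidate LC3, fell by 1.39, and adjusted over the list alone 1 rose and 1 fell. Pro-apoptotic genes gave 0.458 with 0 of 15 called, anti-apoptotic genes 0.817 with 0 of 10, p53 targets 0.876 with 0 of 19, interferon-stimulated genes 0.303 with 0 of 18 and cholesterol synthesis genes 0.843 with 0 of 20, and adjusted over the list alone 0 passed in each. The pro-apoptotic genes Bax and Fas measured 0.53 ± 0.27 and -0.57 ± 0.24. Immediate early genes, which can respond to handling of the cells, gave 0.895, and Dusp1 fell by 1.72 as the 1 called of 13 on both bases, while the list's median of -0.01 lay opposite to camera's upward direction. Some of these lists passed in alternatives: upward, mitochondrially encoded genes in 4 of 24 (adjusted p from 2.0e-12, after the correction for GC content and length, to 0.0264), oxidative phosphorylation in 3 (0.000554 to 0.0102), NF-kB targets in 2 (0.0153 and 0.0251), and ribosomal protein (0.000554) and autophagy and lysosome genes (0.0483) in 1. Downward, with the nuclear RNA index, cholesterol synthesis genes passed (0.0293), as did oxidative phosphorylation (6.4e-13) and ribosomal protein genes (4.5e-25). The estimated correlations of oxidative phosphorylation, ribosomal protein and mitochondrially encoded genes, 0.738, 0.927 and 0.762, lie far above the preset behind these p-values.

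Of markers of other cells the gate could hold, those of T cells passed camera in their own family of 4 lists (adjusted p = 0.0165; adjusted p = 0.142 with an estimated correlation), with 4 of 18 listed genes abundant enough to test, a median log2 fold change of 1.42 and 1 member higher over all genes and over the list alone. That member was Trbc2, a T cell receptor constant gene, at a log2 fold change of 4.77 ± 1.08 (edgeR adjusted p = 0.0190) from 0.0984 ± 0.197 CPM in Control (SD, n = 4) to 3.09 ± 1.66 CPM in MIZ1KO (SD, n = 3). The list's call ended without MIZ1KO replicate 2 (adjusted p = 0.919) or Control replicate 1 (0.455), among protein-coding genes only (0.368), after the correction for GC content and length (0.112), with the nuclear RNA index (0.147), in limma-voom (0.0572) and on the deposited log2 values (0.0520). T cell receptor constant genes are not of the protein-coding class, so the fit to that class lacked Trbc2 and cannot speak for or against its rise. Cd3e averaged 8.09 CPM of the counts outside ribosomal RNA in MIZ1KO, from 1.32 in replicate 1 to 16.8 in replicate 3, and 0.290 in Control. Trac averaged 2.94 and 0.137, and Lck 71.6 and 60.1. Every listed T cell marker with counts averaged higher in MIZ1KO than in Control, at a few CPM apart from Lck, and Il21 had no counts. In MIZ1KO replicate 1 many of them lay within the range of the Control libraries. Macrophage, erythroid and naive B cell markers each had a camera adjusted p of 0.814 and 0 of 6, 7 and 13 tested members called; adjusted over the list alone 1 macrophage and 1 naive B cell marker were higher. The erythroid list passed downward without MIZ1KO replicate 3 (0.0130). Camera's direction was opposite to the median for the erythroid list, down with 0.01, and for the naive B cell list, up with -0.02. Lyz2 averaged 21.3 CPM of the counts outside ribosomal RNA in MIZ1KO (4.19, 26.5 and 33.0 in replicates 1 to 3) and 6.57 in Control, Mpeg1 45.5 and 34.9, Hbb-bs 253 (49.6, 191 and 518) and 270 (118 to 449.9), and Fcer2a, of the naive B cell list, 549.9 and 509. Granulocyte, dendritic cell and stromal lists had fewer than 3 members abundant enough to test: S100a9 averaged 3.67 (11 in replicate 2 and 0 in the others) and 2.24, Flt3 33.1 and 42.1, and Mfge8 0.982 and 2.45.

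**Figure D5:**
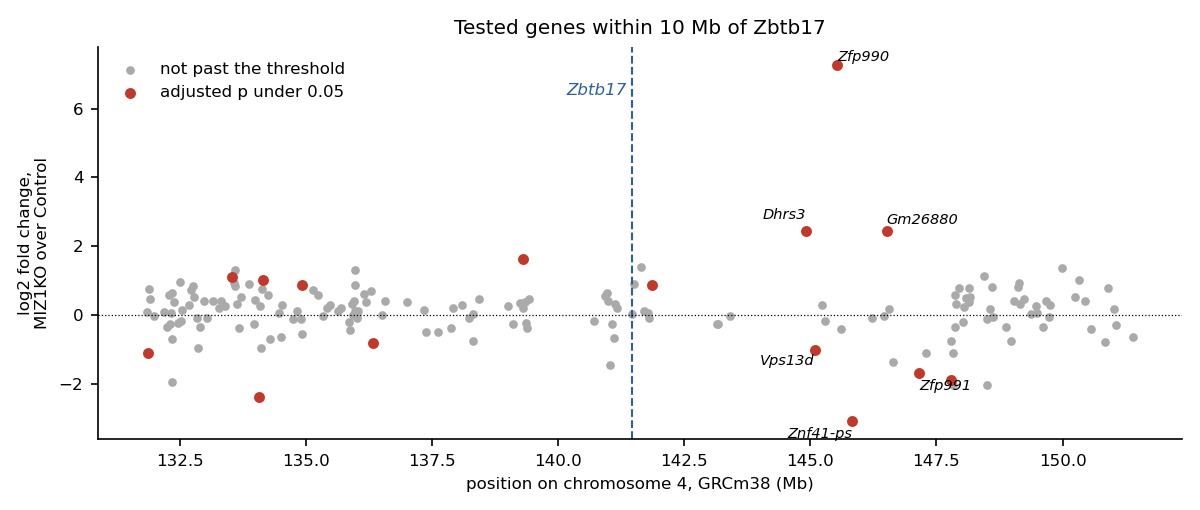
Log2 fold change of MIZ1KO over Control for the 176 tested genes within 10 Mb of Zbtb17 against their position on chromosome 4 of GRCm38 in Mb; red points are genes past an adjusted p of 0.05, grey points the others, and the dashed line marks Zbtb17. Of these genes 15 passed, among them Dhrs3 at 2.45.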

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

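The tests of the chance groupings of libraries and of the ratio of models to their host genes were planned before their results were seen; the tests of GC content and length, of chromosome 4 and its stretch, of the protein-coding background and of the nuclear RNA index were chosen only after related results were seen.

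In 9 of 142 tested sets of the 4 Control values, 1 library stood apart from the rest by more than Dixon's 95% critical value for 4 samples, where chance gives 7.1. Control 1 stood apart in 5: Ighm took 78.4% of its heavy chain constant counts (95% Clopper-Pearson interval 77.9 to 79.0, counting error only) against 81.8% to 82.2% in the others, and Ighg1 took 14.6% (14.2 to 15.1) against 10.4% to 10.6%. Its Scand1 was 12.1 CPM against 4.20 to 4.51, its Mef2b 64.0 CPM against 28.6 to 34.1 and its Gpi1 139 CPM against 86.1 to 94.2. Control 2 was low in Mypopos, at 15.2 CPM against 27.95 to 29.97, in Bax, at 11.7 CPM against 13.2 to 13.5, and in Kif23, at 35 CPM against 39.8 to 40.7. In Control 4, Zbtb17 was 7.02 CPM against 3.15 to 3.42.

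The 692 called genes were more than any other split of the 7 libraries gave: 1 of 35 splits, the real one, reached that count. This is the smallest share the test allows, and it argues against a random labelling of the libraries. Another split came close, so a grouping along some other difference between the libraries cannot be excluded. The highest other split gave 619 and set Control 2, Control 3 and Control 4 against the rest, which points to a structure that places Control 1 nearer to the MIZ1KO libraries. The TEC share follows the same order. It was 1.02% in Control 1, 1.62% to 2.58% in the other Control libraries and 0.544% to 0.923% in MIZ1KO. That split thus also runs along the nuclear RNA share. For the 8 called lists, 6 of 35 splits gave as many, with 13 as the highest of the others, so chance cannot be excluded.

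TEC models and other non-coding RNAs were lower in MIZ1KO. For 380 TEC models inside 266 coding genes, the median log2 ratio of model to host gene was -3.93 ± 0.267 in MIZ1KO (SD, n = 3) and -2.81 ± 0.258 in Control (SD, n = 4), a difference of -1.12 without overlap (two-sided exact permutation p = 0.0286, the smallest possible), which is consistent with a smaller share of unspliced RNA in the MIZ1KO libraries. A bias of GC content and length is argued against as the whole cause: after its correction the median over TEC models moved from -1.35 to -0.82, with quartiles of -1.39 and -0.34. Of the 136 models called lower, 23 stayed called: their median log2 fold change went from -1.87 to -1.38 while their median SE stayed at 0.44. Whether the genotype changed nuclear RNA, or recovery of nuclei differed between samples, stays open and was not tested.

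The calls near Zbtb17 were compared with those elsewhere. Within 10 Mb, 15 of 176 genes were called against 671 of 11414 elsewhere, an odds ratio of 1.49 (95% interval 0.811 to 2.55; Fisher's exact test p = 0.145). For called genes with an absolute log2 fold change of at least 2 it was 5 against 174, an odds ratio of 1.89 (95% interval 0.598 to 4.58; Fisher's exact test p = 0.20). The calls were not spread evenly: 7 of 16 neighbouring genes from Dhrs3 to Gm20707, 3.42 to 6.34 Mb from Zbtb17 and picked after their values were seen, were called, 3 higher and 4 lower. They were Dhrs3 (2.45), Vps13d (-1.01), Zfp990 (7.27, with 101, 56 and 30 counts in the MIZ1KO libraries and 1 count in the 4 Control libraries together), Znf41-ps (-3.10), Gm26880 (2.44), Zfp991 (-1.70) and Gm20707 (-1.89), and outside the stretch Crybg2 measured -2.40. In a permutation test that shuffled the calls among all genes, 11 of 9999 shuffles put as many into any 16 neighbours within the 10 Mb (permutation p = 0.0012), and 632 did anywhere in the genome (permutation p = 0.0633). In the real data 5 regions of the genome reached 7 of 16, and the calls in the other 4 were all lower. Shuffling takes neighbours to be independent, which overlapping models are not. The length of 16 genes was also taken from the stretch of Dhrs3 to Gm20707. The shuffles allow only for its place, so both permutation p-values are likely too small. Strain variants carried with a targeted allele may raise such calls, and would gather near the gene as this stretch does, while the first interval spans both no excess and more than 2-fold. Linked variants would differ between the same libraries as the genotype does, so they cannot be told apart from its effect. Dhrs3 is in this stretch, and Rpl22 lies 10.9 Mb away, just outside the counted window, so the changes of both stay open to linkage.

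The parts named here were formed after the outcome was seen, so each list rests on its own value and their number is no test. Of 6 lists higher in MIZ1KO, 3 stayed called among protein-coding genes by camera at its preset correlation: MYC-activated (adjusted p = 0.00274), G2/M and BCR signalling genes (0.0149 each). At that preset this argues against falling non-coding genes in the background as their whole cause. Of G1/S, glycolysis and unfolded protein response genes 0 stayed called, with medians that went from 0.28 to 0.25, from 0.34 to 0.32 and from 0.13 to 0.10, so for them that cause stays open. Of 7 lists, 5 stayed called at the preset after the correction for GC content and length (camera adjusted p up to 0.0267, for G1/S), which argues against that bias as their whole cause. It stays open for glycolysis and unfolded protein response genes, of which 0 stayed called, with medians of 0.07 and 0.28 after the correction. With the estimated correlation 0 of 27 lists were called in the main fit, so both arguments hold only as far as the preset does. With the nuclear RNA index as a covariate 1 list, BCR signalling, stayed called, but the index did not overlap between the groups, so the nuclear RNA share and the genotype cannot be told apart. A biological difference between the genotypes stays open as well, and was not tested apart from these.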

How the results depend on the processing

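Leaving out ribosomal RNA genes, protein-coding genes only, the correction for GC content and length, and the nuclear RNA index were chosen after seeing the data. Over 3604 alternative values, 2950 kept their direction and their side of the threshold. These include results not called in the main fit, which have no call to lose. Another 81, over 44 results, turned direction without a call before or after, and 52 counts stayed within 1.5 times the main one. The threshold was lost by 326 and gained by 140, 46 counts moved and 9 turned direction with a call on at least 1 side. Of the 45 named calls, 37 ended without at least 1 library. Unless said otherwise the cause was not tested. Zbtb17 stayed uncalled in the 21 alternatives that gave it a value, with log2 fold changes from -0.41 to 0.51 and the sign turning among them; the stricter filter removed it. With 3 and 4 libraries of 3087992 to 5085019 counts outside ribosomal RNA, 27.4% of simulated 2-fold changes were recovered, so smaller changes can go unseen. The number of called genes, 692 (221 higher, 471 lower), was 1067 in DESeq2 (415 higher), 319 in limma-voom (118 higher, 201 lower), 468 in the legacy fit, 294 after the correction for GC content and length (136 higher, 158 lower; 46.3% higher against 31.9%) and 27 against a minimum fold change of 1.5 (9 higher, 18 lower), which asks for more. It was 315 in a fit to protein-coding genes only (140 higher, 175 lower, of 9841 tested), while the main fit called 406 of 9812 protein-coding genes. Without a filter the median of all genes was -0.14. The log2 fold change of Tmbim4 was -2.92 against a minimum fold change of 1.5 (adjusted p = 0.0957) and -2.71 in limma-voom (0.0907), and over all its alternatives it ran from -5.56 with the nuclear RNA index to -0.82 on the deposited log2 values.

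Of the 8 called lists, 0 were called with an estimated correlation (adjusted p = 0.487 for heavy chain constant genes, 0.530 for glycolysis and 0.525 for the other 6), 2 by fry and 5 by a rank-based camera. Fry gave 0.219 for MYC-activated, G1/S and unfolded protein response genes, 0.101 for reported MIZ1 targets and G2/M genes and 0.298 for glycolysis. The rank-based camera gave 0.285 for reported MIZ1 targets, 0.0869 for the unfolded protein response and 0.0587 for glycolysis. With no filter 13 lists were called, and reported MIZ1 targets gave 0.0643; with the stricter filter 5 were, and G1/S and unfolded protein response genes gave 0.0592 and glycolysis 0.0879. Without immunoglobulin genes 4 were called, and reported MIZ1 targets, unfolded protein response and glycolysis genes each gave 0.0512, in a smaller family of lists. Among protein-coding genes only 4 were called, with 0.128 for G1/S and glycolysis and 0.167 for the unfolded protein response. After the correction for GC content and length the unfolded protein response gave 0.0854 and glycolysis 0.532. Scaling to library totals gave 0.0593 for the unfolded protein response, and reported MIZ1 targets gave 0.0935 in limma-voom and 0.0763 on the deposited log2 values.

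With the nuclear RNA index as a covariate 144 genes were called (15 higher, 129 lower), 16 of them among the 692, and the log2 fold changes of Xist (0.0874) and Atp5d (-0.0313) changed sign. Lists turned downward for MYC-activated (adjusted p = 0.0668), G1/S (0.691), G2/M (0.950), unfolded protein response (0.950), glycolysis (0.163), oxidative phosphorylation (6.4e-13) and ribosomal protein genes (4.5e-25), and heavy chain constant genes gave 0.0980. For oxidative phosphorylation and ribosomal protein genes the preset correlation lies far below the estimates of the main fit, 0.738 and 0.927, with which they gave 0.900 and 0.932 there, so these p-values rest on the preset. The index does not overlap between the groups, so this fit rests on its spread within them.

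Control and MIZ1KO libraries with the same replicate number had correlations of their deviations of 0.0233, 0.0665 and 0.162, and MIZ1KO 2 correlated best with Control 1 (0.134), so the numbers were not taken to pair samples. With the replicate block 476 genes were called, 131 of them higher, and 5 lists, with 0.0603 for G1/S and 0.0722 for unfolded protein response and glycolysis genes.

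With 1 library left out, 39 genes (without MIZ1KO replicate 1) to 1350 (without Control replicate 1) were called, 22 to 523 of them higher and 17 to 827 lower; the higher calls outnumbered the lower without MIZ1KO replicate 1 (22 against 17) and without MIZ1KO replicate 2 (299 against 196). Of the 45 named calls, only Adam19, Lrrc18 and Tmbim4 moved by more than 1.5 times in fold change. The log2 fold change of Adam19 went from 1.82 to 0.96 without MIZ1KO replicate 2 and that of Lrrc18 from -1.78 to -2.45 without MIZ1KO replicate 3. That of Tmbim4 ranged from -3.18 to -2.23, and was -3.04 and -2.44 where its call ended. Between 4 and 11 lists were called, 4 without Control replicate 2 and 5 without Control replicate 4. Adjusted p ranged from 0.0173 to 0.242 for reported MIZ1 targets, 0.00635 to 0.0517 for G1/S, 0.0117 to 0.130 for unfolded protein response and 0.00574 to 0.114 for glycolysis genes.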

Other observations

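The tests of GC content named here were chosen only after the gene calls were seen. Several genes outside the naming rule, chosen after their values were seen, had large changes in MIZ1KO: Mir17hg, the host transcript of the miR-17 cluster, had a log2 fold change of -3.02 ± 0.51 (edgeR adjusted p = 0.00612), Dctn6, a dynactin subunit, -3.27, and Exoc2, a subunit of the exocyst, -1.47 ± 0.26 (edgeR adjusted p = 0.00749).

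Genes called higher in MIZ1KO had a median GC content of 55.7% and those called lower 42.1%, against 48.4% over all tested genes. Among protein-coding genes the medians were 55.8% and 42.8%.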
